A study of Mus musculus with 6 samples.

How the data were processed

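The samples were 6 bulk RNA libraries from cells of the cerebrospinal fluid of mice with experimental leptomeningeal metastasis. Per the labels' protocols, the cells were sorted by flow cytometry into medium with serum, total RNA was isolated with a column kit, and libraries from RNA with an integrity number above 7 were sequenced on an Illumina NovaSeq instrument as read pairs of 150 bp. The series' design text speaks of 10 samples, of which 3 resident macrophage and 3 monocyte-macrophage libraries were analysed here. Groups and replicate numbers came from the sample titles and cell type labels. Nothing in the labels says whether libraries of 1 group came from separate mice, so p-values measure the spread between these libraries, which may be technical in part. Sex-linked RNA, reported below, differed between libraries of the same group, so these were not all repeats of 1 RNA sample.

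Expression was deposited by the authors as FPKM, fragments scaled by gene length and by the library's total, in 1 table of 34652 genes and 6 columns, each of which matched 1 library. FastQC, HISAT2 and featureCounts with genome build mm10 are named per the submitters' processing notes. Their versions, settings, strand handling and annotation, and the gene length and fragment total behind the FPKM, are not given in the sources used here. The labels do not say how reads that map to several places were treated. Genes with near-identical copies or many processed pseudogenes, such as Ly6c1 and Ly6c2, H2-Q6 and H2-Q7, the clustered histone and globin genes, and Gapdh, are therefore uncertain in level. The same holds for overlapping and antisense genes.

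The deposited FPKM values are not counts, so no count model was used. Depth was estimated from the values. In each library the lowest values of a gene are steps of 1 read, and the gene symbols of 32672 genes (94.3%) matched 1 gene of the GENCODE M21 annotation on mm10. With the exon lengths of that annotation, the steps gave 1.48e+07, 1.23e+07 and 1.24e+07 fragments for resident macrophage libraries 1, 2 and 3, and 1.37e+07, 1.41e+07 and 1.70e+07 for monocyte-macrophage libraries 1, 2 and 3. Relative depths from the steps alone, with no lengths, were 0.832, 0.839, 0.925, 0.950 and 1.15 times resident macrophage library 1 for the other libraries in that order, against 0.832, 0.839, 0.925, 0.950 and 1.15 with lengths. Between 40.4% and 44.1% of the values below 20 reads came out whole within 0.02 reads, so counts were not recovered. A gene with 2 kb of exon gains between 0.0294 and 0.0406 FPKM per read. These are estimates of counting precision only. Some zeros in the table may be missing values: 4 genes are listed at 0 in 1 library and above 5 FPKM in the other libraries, among them the mitochondrial gene mt-Co1 in resident macrophage library 2 and the immunoglobulin gene Igkc in monocyte-macrophage library 2. Where a library is listed at 0, the text says so and gives no mean of FPKM for that group and no ratio of means, while the log2 fold change on the log2(FPKM + 1) scale is still given. Rpph1, an RNA of ribonuclease P, had the highest FPKM in each library, between 8.61% and 15.8% of the sum of FPKM. No pair of libraries held identical values.

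Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, 11317 in all. Values were transformed as log2(FPKM + 1) and fitted in limma 3.58.1 (R 4.3.3) with 1 term for the group and empirical Bayes moderation with a mean-variance trend. P-values were adjusted by the Benjamini-Hochberg method, and a gene passed at an adjusted p under 0.05. Log2 fold changes are resident macrophages minus monocyte-macrophages on the log2(FPKM + 1) scale, which understates the change of genes with low values, and are given with their standard error (SE). Means of FPKM are given with their standard deviation (SD) over 3 libraries, and folds are ratios of these means. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

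Before the data were examined, 42 gene lists with 710 genes were fixed, of which 708 were in the table. They covered the genes of the sort, border macrophages, microglia, classical and non-classical monocytes, MHC class I and II, costimulation and checkpoints, genes induced by type I interferon and by interferon gamma, inflammatory cytokines, chemokines, cytokine receptors, migration and adhesion, complement, scavenger receptors and efferocytosis, Fc and Toll-like receptors, lysosome, lipid handling, cholesterol synthesis, glycolysis and hypoxia, the respiratory chain, iron and heme, tumor macrophages, matrix remodeling, growth factors, transcription factors, cell cycle and handling stress. Lists of other cell types covered T cells, natural killer (NK) cells, B and plasma cells, neutrophils, conventional and plasmacytoid dendritic cells, mast cells with basophils and eosinophils, carcinoma cells, meningeal fibroblasts, endothelial cells, red cells and platelets, and neural and choroid plexus cells. A list of sex-linked genes served only to check the libraries. The 39 other lists with at least 3 tested members were tested with limma's camera, which compares a list with the other tested genes, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list, and fry, which tests a list alone, were run beside it. Gene calls were also adjusted over the list alone. With 3 libraries in each group an exact permutation test cannot give a p below 0.1, so single genes were tested in limma only.

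The genes named were chosen by a rule fixed at the same time: the 6 sort genes; the 12 genes with the largest change in each direction among those that passed, whose groups did not overlap and whose mean FPKM in the higher group was at least 10, leaving out gene models, mitochondrial, ribosomal protein and immune receptor segment genes; up to 4 members of each list with the smallest adjusted p, filled to 2 with the members of highest FPKM where fewer passed; members that moved against their list; and the 2 members of highest FPKM in lists of other cell types. Some genes that the rule names are not reported here. Other named genes were chosen after their values were seen, and they stand in the report as further members of a list or its members that did not pass. Coordinates are from GENCODE M21 on mm10, counted from 1.

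The gene test was tried on simulated data for the comparison of resident macrophages with monocyte-macrophages. Counts were drawn for the real genes at the real depths with a dispersion of 0.02, and 200 genes were changed. Of the 11276 genes tested, 66 had a 1.5-fold, 67 a 2-fold and 66 a 4-fold change. The test recovered 27.3% of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes, with 8 false calls, 5.19% of the calls. Fitted log2 changes were 0.815, 0.819 and 0.834 times the true ones in these classes.

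Alternatives chosen before the data were examined were a pseudocount of 0.1; no filter; a filter of 5 FPKM; rescaling to a fixed sum (TPM scale), median-of-ratios scaling and quantile normalization; robust empirical Bayes; library weights; the replicate number as a block; each library left out in turn; an absolute log2 fold change of at least 1; and an adjusted p under 0.01. A term for the libraries with more Y-linked RNA, and a fit of the 4 libraries with less, were chosen after seeing the data.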

Results

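The data compared 2 populations of macrophages from the cerebrospinal fluid of mice 12 days after inoculation with LLC-LeptoM cells, a Lewis lung carcinoma line that grows in the leptomeninges. The mice carried a tamoxifen-inducible Cre under control of Cx3cr1 and a membrane reporter that switches from red to green fluorescence in cells where Cre has acted. Resident macrophages were sorted as green cells with CD45, CD11b and F4/80 and without Ly6C. Monocyte-macrophages were sorted as cells without green fluorescence, either with F4/80 or with low F4/80 and Ly6C, and both fractions were mixed. There were 3 libraries of each population. The estimated number of fragments per library lay between 1.23e+07 and 1.70e+07, and between 10281 and 11470 genes reached 1 FPKM. The comparison asks how resident macrophages of the cerebrospinal fluid differ in expression from macrophages that derive from monocytes in the same model.

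Complement C1q, MHC class II and a set of chemokines were far higher in the resident macrophage libraries, and most classical monocyte (18 of 20) and cell cycle genes (26 of 30) were lower. Most histone genes (59 of 66) and granule protein genes, groups put together after the values were seen, were lower as well. In the same libraries all 20 T cell markers, 14 of 16 dendritic cell markers, Ccl22 among them, 8 of 9 B and plasma cell markers and 4 of 5 markers of mast cells, basophils and eosinophils were higher too. Of 11317 genes tested, 2249 were higher and 1204 lower in resident macrophages, together 30.5%. An absolute log2 fold change of at least 1 was reached by 883 of the higher and 428 of the lower genes. For 46.2% of the genes the 3 libraries of one group all lay above the 3 of the other, where chance gives 10%. Libraries of one group correlated with each other across genes at r between 0.966 and 0.979, and libraries of different groups at r between 0.876 and 0.905; genes are not independent replicates. The first principal component held 72.8% of the variance and separated the groups. The balance of directions depended on the scaling: 65.1% of the called genes were higher as deposited, 68.7% on the TPM scale, 51.9% with median-of-ratios scaling (1798 higher, 1664 lower) and 51.4% with quantile normalization (1799 higher, 1702 lower). Quantile normalization moved the median log2 fold change of all genes by -0.11, from 0.06 to -0.05. Of the 3453 called genes, 3001 were also called with median-of-ratios scaling and 2898 with quantile normalization. Y-linked RNA was higher in resident macrophage library 3 and monocyte-macrophage library 2 than in the other libraries: Ddx3y was at 2.21, 2.10 and 10.1 FPKM in resident macrophage libraries 1 to 3 and at 1.56, 10.6 and 2.68 in monocyte-macrophage libraries 1 to 3. Xist, transcribed from the inactive X chromosome, was at 52.3, 40.3 and 10.5 against 45.5, 10.6 and 58.2 FPKM. None of the 3 tested sex-linked genes differed between the groups (log2 fold changes -0.11 for Xist, 0.01 for Ddx3y and 0.03 for Eif2s3y). With a term for this split 2408 genes were higher and 1311 lower, and within the 4 libraries with less Y-linked RNA 1480 were higher and 780 lower; the remaining pair has 1 library per group and allows no test. Without resident macrophage library 2, 780 genes were lower.

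**Figure D1:**
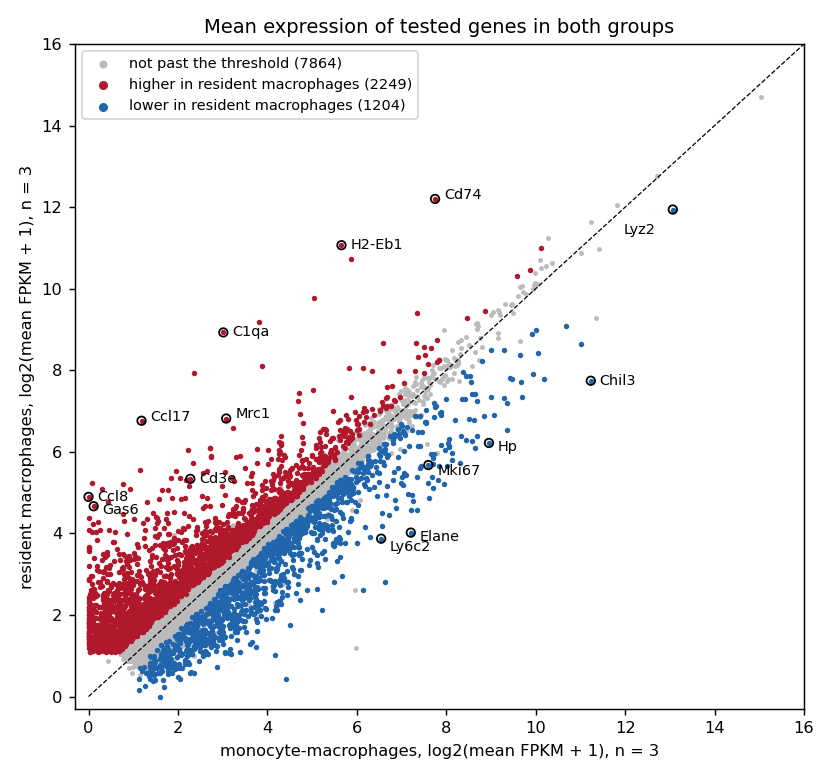
Mean expression of the 11317 tested genes as log2(mean FPKM + 1), monocyte-macrophages on the x axis and resident macrophages on the y axis, 3 libraries each. Red points are the 2249 genes higher and blue points the 1204 genes lower in resident macrophages at an adjusted p under 0.05 in limma, grey points the 7864 that did not pass, and circles mark named genes such as C1qa (log2 fold change 5.93) and Chil3 (-3.50).

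The genes behind the sort gates followed the gates in part. Ly6c2, which encodes a Ly6C antigen of inflammatory monocytes (chromosome 15, 75108158 to 75111970), was 6.77-fold higher in monocyte-macrophages, at 92.3 ± 28.2 FPKM against 13.6 ± 1.85 in resident macrophages (SD, n = 3). Cx3cr1, the chemokine receptor whose locus drives Cre, was higher in resident macrophages at 27.4 ± 6.12 against 9.16 ± 3.80 FPKM (SD, n = 3; log2 fold change 1.53, SE 0.29, adjusted p = 0.0066). Ly6c1, a near-identical neighbour of Ly6c2, was lower in resident macrophages, at 1.11 ± 0.0694 against 7.79 ± 2.93 FPKM (SD, n = 3). Adgre1, which encodes F4/80, was higher by 0.60 with an adjusted p of 0.040, a call lost without any of 5 single libraries, with median-of-ratios scaling and without a filter (adjusted p = 0.079). Ptprc (CD45) and Itgam (CD11b) did not pass, with log2 fold changes of -0.19 and -0.30; median-of-ratios scaling put both past the threshold, lower in resident macrophages, and quantile normalization put Itgam past it. As a list, 2 of these 6 genes were higher and 2 lower, or 2 and 3 adjusted over the list alone. The list did not pass camera (adjusted p = 0.12, and adjusted p = 0.44 with an estimated correlation), but passed without a filter (adjusted p = 0.039). Being used for sorting, these genes describe the gates and are not findings.

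The genes with the largest rises included complement, MHC class II and chemokine genes. C1qa, C1qb and C1qc, the 3 chains of complement C1q, lie next to each other on chromosome 4 (136880129 to 136898803 from the start of C1qb to the end of C1qa). C1qa stood at 486 ± 80.6 FPKM in resident macrophages and 7.08 ± 2.02 in monocyte-macrophages (SD, n = 3), a log2 fold change of 5.93 with SE 0.20 and an adjusted p of 7.1e-06. C1qc was higher by 5.61 and C1qb by 5.47 on the log2 scale. The MHC class II genes H2-Eb1 (chromosome 17, 34305867 to 34316674), H2-Ab1 and H2-Aa were higher by 5.45, 4.87 and 4.72, with H2-Eb1 at 2144 ± 225 against 49.4 ± 15.4 FPKM (SD, n = 3). Among chemokines, Ccl17 and Ccl22, ligands of Ccr4, and Ccl8 were higher by 5.74, 4.76 and 4.89 on the log2(FPKM + 1) scale, Ccl17 being listed at 0 in monocyte-macrophage library 2. Ccl8 (chromosome 11, 82115185 to 82116799) was listed at 29.9, 32.0 and 24.4 FPKM in the resident macrophage libraries and at 0 in each monocyte-macrophage library. Fcrls, a microglia-associated Fc receptor-like gene, was listed at 50.5, 34.3 and 25.7 FPKM against 0, 0 and 0.154. Gas6, a bridging ligand for the uptake of apoptotic cells, was higher by 4.49 and listed at 0 in monocyte-macrophage library 2, and the C-type lectin gene Mgl2 by 4.46.

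The genes with the largest falls included monocyte, granule protease and histone genes. Chil3, which encodes the chitinase-like protein Ym1 (chromosome 3, 106147554 to 106167564), fell by 3.50 on the log2 scale, from 2403 ± 713 FPKM in monocyte-macrophages to 213 ± 71.2 in resident macrophages (SD, n = 3; SE 0.31, adjusted p = 2.4e-04). Fcnb (ficolin B) fell by 3.47 and Serpinb10 by 3.17. The azurophil granule protease genes Elane (chromosome 10, 79886247 to 79888215) and Prtn3 fell by 3.11 and 2.73, and the neutrophil collagenase gene Mmp8 by 2.66. Hp, which encodes haptoglobin, stood at 495 ± 62.1 FPKM in monocyte-macrophages and 73.4 ± 16.3 in resident macrophages (SD, n = 3), a fall of 2.75. Arhgef37 fell by 2.68 and Serpinb1a by 2.55. The histone genes Hist1h2bj and Hist1h2bk fell by 2.58 and 2.57; both belong to a family of near-identical genes, so the level of each is uncertain.

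The resident macrophage libraries had more RNA of the genes that mark macrophages of the brain's borders and microglia. Of 19 tested border macrophage genes 18 were higher and 1 lower, and adjusted over the list alone the numbers were the same (median log2 fold change 2.54; camera adjusted p = 1.9e-10). The adjusted p was 0.21 with an estimated correlation. The mannose receptor gene Mrc1 stood at 112 ± 7.92 against 7.45 ± 2.83 FPKM (SD, n = 3), and Stab1 and Cd163, both scavenger receptor genes, were higher by 3.28 and 2.54. Timd4, a receptor for phosphatidylserine, was listed at 5.51, 7.14 and 6.08 FPKM in resident macrophages and at 0 in each monocyte-macrophage library. F13a1, which encodes a coagulation factor XIII subunit, moved the other way and fell by 2.35, to 163 ± 23.5 from 830 ± 82.5 FPKM (SD, n = 3). All 14 tested microglia genes were higher, as they were adjusted over the list alone (median 1.91; camera adjusted p = 3.3e-08, and adjusted p = 0.22 with an estimated correlation). Bin1 was higher by 2.19, Gpr34 by 2.71 and Trem2 by 1.98; at a filter of 5 FPKM 9 microglia genes were left and called. Some levels were low: Tmem119 had 9.43 ± 1.06 against 2.31 ± 0.968 FPKM and P2ry12 3.58 ± 0.893 against 1.22 ± 0.276 (SD, n = 3). Of the border macrophage genes, 12 also stand in another of the lists. Markers of T cells (median 2.28), dendritic cells (2.28), B and plasma cells (2.02) and mast cells, basophils and eosinophils (3.50) were higher in the same libraries.

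Complement and uptake receptor genes were mostly higher as well. Of 10 tested complement genes 7 were higher and 1 lower, or 8 and 1 adjusted over the list alone (median 1.48; camera adjusted p = 2.1e-04, and adjusted p = 0.29 with an estimated correlation). The receptor gene C3ar1 was higher by 1.57 and C4b by 2.32, while C3, the central component, fell by 1.71, to 110 ± 16.4 from 362 ± 51.8 FPKM (SD, n = 3). Among scavenger receptor and efferocytosis genes, 12 of 22 were higher and 1 lower, with the same numbers adjusted over the list alone (median 0.58; camera adjusted p = 8.4e-04, and adjusted p = 0.27 with an estimated correlation). The receptor tyrosine kinase genes Axl and Mertk, which bind Gas6, were higher by 3.85 and 2.86. Scarb1, a lipoprotein receptor gene, fell by 0.81, and 9 of the 22 members stand in another list too; 2 were lower without monocyte-macrophage library 1.

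MHC genes of both classes were mostly higher in resident macrophages. Of 13 MHC class II genes 12 were higher, and 13 adjusted over the list alone (median 3.39; camera adjusted p = 1.6e-11, and adjusted p = 0.21 with an estimated correlation). The invariant chain gene Cd74 reached 4707 ± 531 FPKM against 214 ± 28.8 (SD, n = 3), H2-DMb2 was higher by 3.53, and Ciita, the master regulator of the class, by 3.39. Of 15 MHC class I genes 14 were higher, as they were adjusted over the list alone, by smaller steps (median 0.82; camera adjusted p = 5.3e-07, and adjusted p = 0.22 with an estimated correlation). H2-K1 stood at 161 ± 15.3 against 57.5 ± 6.33 FPKM (SD, n = 3) and H2-Q4 was higher by 1.72; H2-Q6 and H2-Q7, higher by 3.42 and 2.40, are near-identical copies. Of 18 costimulation and checkpoint genes 9 were higher and 1 lower, with the same numbers adjusted over the list alone (median 0.66; camera adjusted p = 0.016, and adjusted p = 0.27 with an estimated correlation). Pdcd1lg2, which encodes the checkpoint ligand PD-L2, was higher by 2.39, Icosl by 0.90 and Cd200r1 by 0.83. Tnfsf4 (OX40 ligand) was higher by 1.46 and listed at 0 in monocyte-macrophage libraries 2 and 3, and Lgals3 (galectin-3) fell by 0.91. Cd80 had a log2 fold change of 0.00 and Cd86 of 0.48, which did not pass. At a filter of 5 FPKM the costimulation list no longer passed camera (adjusted p = 0.063). In the same libraries all 16 tested dendritic cell markers but Flt3 and Cd24a were higher in resident macrophages.

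Most tested genes induced by interferon gamma were higher in resident macrophages. Of 21 tested genes induced by interferon gamma, 16 were higher, and 19 adjusted over the list alone (median 0.91; camera adjusted p = 3.3e-08, and adjusted p = 0.11 with an estimated correlation). Serpina3g was higher by 2.77, the GTPase gene Iigp1 by 2.61, and the chemokine gene Cxcl9 stood at 57.7 ± 1.03 against 8.90 ± 2.98 FPKM (SD, n = 3). Of 24 tested genes induced by type I interferon, 0 were higher and 1, Cmpk2, was lower by limma; adjusted over the list alone 0 passed. Camera did not call the list (adjusted p = 0.94, and adjusted p = 0.98 with an estimated correlation), and its direction was down while the median was 0.13. Isg15 stood at 24.1 ± 4.67 against 20.4 ± 6.77 FPKM and Ifit3 at 33.4 ± 3.12 against 28.0 ± 10.6 (SD, n = 3). The fall of Cmpk2 by 0.97 was lost without any of 5 single libraries, and without monocyte-macrophage library 3, 3 genes of this list were higher. The difference between both interferon lists was not tested. T cell markers were higher in the same resident macrophage libraries.

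Chemokine genes were higher in part. Of 21 tested, 13 were higher, and 14 adjusted over the list alone (median 1.91; camera adjusted p = 2.4e-06, and adjusted p = 0.11 with an estimated correlation). Ccl12 was higher by 4.39, with 46.1 ± 7.16 against 1.23 ± 0.229 FPKM (SD, n = 3), and Cxcl16 by 3.42. The inflammatory chemokine genes Ccl2, Ccl3 and Cxcl2 had log2 fold changes of 0.48, 0.44 and 0.52 and did not pass. Without monocyte-macrophage library 2, 1 chemokine gene was called lower. In the same libraries 14 of 16 dendritic cell markers, Ccl22 among them, and all 20 T cell markers were higher in resident macrophages. Of 18 inflammatory cytokine genes 4 were higher and 2 lower, as they were adjusted over the list alone (median 0.01; camera adjusted p = 0.94, and adjusted p = 0.98 with an estimated correlation). Traf1 was higher by 1.47, Il12b, listed at 0 in monocyte-macrophage library 2, by 2.29 and Tnfaip3 by 1.26, and Lcn2 fell by 2.25; Il1b had 153 ± 52.6 against 166 ± 89.4 FPKM (SD, n = 3). In that list 2 genes were higher without resident macrophage library 3 or monocyte-macrophage library 1, 0 were lower without resident macrophage library 2 or monocyte-macrophage library 2, and 5 were lower with the term for Y-linked RNA. Only 1 was lower without resident macrophage library 1 or 3 or monocyte-macrophage library 1 or 3. The calls of Tnfaip3 and Lcn2 each ended without any of 4 single libraries.

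Receptor lists held members in both directions. Of 23 cytokine receptor genes 8 were higher and 4 lower, or 10 and 7 adjusted over the list alone (camera adjusted p = 0.88, and adjusted p = 0.98 with an estimated correlation); the median was -0.03 and the mean 0.25. Tgfbr2 stood at 65.5 ± 6.11 against 18.2 ± 4.73 FPKM (SD, n = 3), Tgfbr1 was higher by 1.21 and Il7r by 2.05, and Il17ra fell by 1.33. Without resident macrophage library 1 or 2, 2 receptor genes were lower, and with median-of-ratios scaling 7. Of 25 migration and adhesion genes 10 were higher and 6 lower, or 10 and 10 adjusted over the list alone (camera adjusted p = 0.89, and adjusted p = 0.93 with an estimated correlation). The median of that list was -0.29 and its mean 0.37. The median was -0.16 without resident macrophage library 2, -0.13 without monocyte-macrophage library 1 and -0.14 without monocyte-macrophage library 2, and with median-of-ratios scaling 10 genes were lower. Itgax, which encodes CD11c, stood at 40.0 ± 0.828 against 3.10 ± 0.0779 FPKM (SD, n = 3), Ccr7 was higher by 4.33 and Itga6 by 1.88, and Ccr2 fell by 0.77. Itgax and Ccr7 also stand among the dendritic cell markers, 14 of 16 of which were higher, and Il7r among the T cell markers, all 20 of which were higher. Of 20 Fc and Toll-like receptor genes 5 were higher and 2 lower, or 6 and 4 adjusted over the list alone (median 0.02; camera adjusted p = 0.94, and adjusted p = 0.98 with an estimated correlation). Tlr3 was higher by 1.92, Fcgr2b by 1.26, Tlr1 by 0.88 and Fcgr4 by 0.92. The lower members were Tlr5 and Tlr6; their number was 1 without resident macrophage library 1 or 3 or monocyte-macrophage library 1 or 3, 0 without resident macrophage library 2, and 4 with median-of-ratios scaling.

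Classical monocyte genes were lower in resident macrophages. Of 20 tested, 18 were lower, and 19 adjusted over the list alone (median -1.32; camera adjusted p = 3.0e-13, and adjusted p = 0.21 with an estimated correlation). Cd177 stood at 26.7 ± 3.78 against 152 ± 33.0 FPKM (SD, n = 3), a fall of 2.45. Of these 20 genes 8 stand in another list too, and in the same libraries 7 of 18 neutrophil markers were lower (median -0.95; camera adjusted p = 2.3e-04, and adjusted p = 0.39 with an estimated correlation). Ccr2, the receptor for monocyte egress from bone marrow, fell by 0.77, and the lysozyme gene Lyz2 by 1.12. Of 10 non-classical monocyte genes 1 was higher and 3 lower, or 2 and 3 adjusted over the list alone (median -0.31; camera adjusted p = 0.22, and adjusted p = 0.37 with an estimated correlation). Cd36 was higher by 1.52, and Adgre4, Itgal and Pglyrp1 fell by 0.88, 0.51 and 1.36. Without resident macrophage library 1, 1 of them was lower, and without resident macrophage library 3, 0; 2 genes were higher without monocyte-macrophage library 3. The median was -0.17 without resident macrophage library 1 and -0.16 without monocyte-macrophage library 1. At a filter of 5 FPKM this list passed camera (adjusted p = 0.036).

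Cell cycle genes formed the list with the smallest camera p. Of 30 tested, 26 were lower in resident macrophages and 27 adjusted over the list alone (median -1.34; camera adjusted p = 3.9e-16, and adjusted p = 0.27 with an estimated correlation). Mki67, a marker of cycling cells (chromosome 7, 135689784 to 135716361), stood at 50.1 ± 5.09 FPKM in resident macrophages and 193 ± 35.4 in monocyte-macrophages (SD, n = 3). Rrm2, a subunit of ribonucleotide reductase, fell by 1.92, Ccnb2 by 1.75 and Plk1 by 1.81. The 4 members that did not pass, Mcm2, Mcm3, Mcm4 and Mcm6, encode parts of the replicative helicase and had log2 fold changes of -0.07, 0.02, -0.33 and -0.11. In the same libraries part of the neutrophil markers were lower, several granule protein genes among them. Neutrophil markers counted 7 lower and 0 higher of 18, or 9 lower adjusted over the list alone (median -0.95; camera adjusted p = 2.3e-04, and adjusted p = 0.39 with an estimated correlation). Elane stood at 15.2 ± 2.31 against 147 ± 56.5 FPKM (SD, n = 3), Mpo fell by 2.33, Camp by 2.41 and Ngp by 2.06. S100a9 was at 620 ± 83.9 against 2623 ± 1851 FPKM (SD, n = 3) and did not pass (adjusted p = 0.058), but passed without monocyte-macrophage library 1. Without any one of the resident macrophage libraries, or without monocyte-macrophage library 2, 3 neutrophil genes were lower. The calls of Camp and Ngp were among those lost. The median of this list was -1.64 with 9 lower genes without monocyte-macrophage library 1 (camera adjusted p = 9.5e-09), and -0.64 with 5 lower genes without monocyte-macrophage library 3 (camera adjusted p = 8.1e-04).

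**Figure D2:**
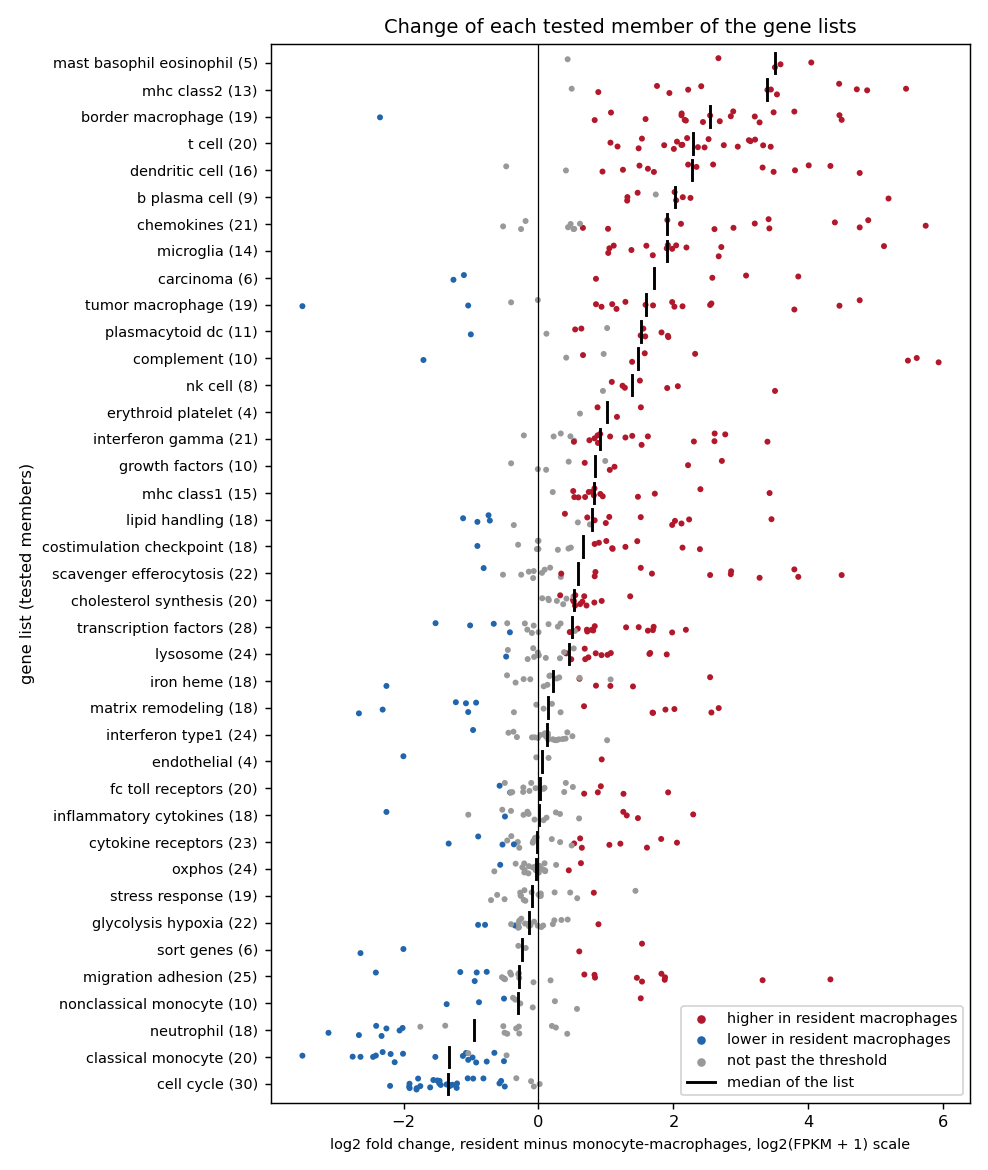
Log2 fold change (resident macrophages minus monocyte-macrophages, log2(FPKM + 1) scale, x axis) of each tested member of the 39 gene lists (y axis, number of tested members in brackets), with list medians as black bars. Red points passed upward, blue points passed downward and grey points did not pass at an adjusted p under 0.05. Medians run from 3.50 for mast cells, basophils and eosinophils (5 tested members, 0.74 over 12 members without a filter) to -1.34 for the cell cycle.

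Cholesterol, lipid and lysosome genes were higher in part. Of 20 cholesterol synthesis genes 13 were higher, as they were adjusted over the list alone (median 0.52; camera adjusted p = 1.1e-04, and adjusted p = 0.27 with an estimated correlation). The regulator gene Srebf2 stood at 59.9 ± 3.34 against 30.9 ± 3.80 FPKM (SD, n = 3), and Sqle and Fdft1 were higher by 0.83 and 0.62. The number was 8 without resident macrophage library 1 and 7 without resident macrophage library 2 or with quantile normalization. Of 18 lipid handling genes 11 were higher and 4 lower, as they were adjusted over the list alone (median 0.80; camera adjusted p = 0.048, and adjusted p = 0.34 with an estimated correlation). Apoe, a lipid carrier, stood at 674 ± 40.0 against 162 ± 66.0 FPKM (SD, n = 3), and Pltp, Acp5 and Ch25h were higher by 3.45, 2.02 and 2.23, Ch25h being listed at 0 in monocyte-macrophage libraries 1 and 2. Apoc1, Plin2, Soat1 and Lgals3 fell. This list did not pass camera on the TPM scale (adjusted p = 0.068), with a pseudocount of 0.1 (adjusted p = 0.067), without a filter (adjusted p = 0.056), at a filter of 5 FPKM (adjusted p = 0.32) or without resident macrophage library 1 (adjusted p = 0.089). Of 24 lysosome genes 12 were higher and 1 lower, or 14 and 1 adjusted over the list alone (median 0.45; camera adjusted p = 0.018, and adjusted p = 0.27 with an estimated correlation). Ctsd, a lysosomal protease gene, stood at 252 ± 66.6 against 80.4 ± 21.5 FPKM (SD, n = 3), Tpp1 was higher by 0.74 and Gusb by 0.69, and Lamp2 fell by 0.48. Without resident macrophage library 1, 7 lysosome genes were higher; 0 were lower without resident macrophage library 2 and 2 without resident macrophage library 3.

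Energy and iron genes changed in small numbers. In the glycolysis and hypoxia list 1 of 22 was higher and 3 lower, or 1 and 2 adjusted over the list alone (median -0.14; camera adjusted p = 0.14, and adjusted p = 0.77 with an estimated correlation). Pdk1 was higher by 0.89, and Ndrg1, Ero1l and Gpi1 fell by 0.89, 0.79 and 0.35; the number of lower genes was 1 without resident macrophage library 2 or 3 or monocyte-macrophage library 2 or 3, and 2 were higher without resident macrophage library 3. That list passed camera without resident macrophage library 1 (adjusted p = 0.0064) and without a filter (adjusted p = 0.0497). Of 24 respiratory chain genes 2 were higher and 1 lower, or 1 and 0 adjusted over the list alone (median -0.03; camera adjusted p = 0.22, and adjusted p = 0.59 with an estimated correlation). Atp5g3 was higher by 0.45 and Cox7c by 0.63, and Ndufb3 fell by 0.57; the call of Cox7c and that of Ndufb3 each ended without any one resident macrophage library and without a filter. The number of lower genes was 1 without resident macrophage library 1, 0 without resident macrophage library 2 or 3, 2 without monocyte-macrophage library 1 or with quantile normalization, and 4 with median-of-ratios scaling. Only 1 was higher without any one resident macrophage library or monocyte-macrophage library 1, on the TPM scale, and with quantile or median-of-ratios scaling. Of 18 iron and heme genes 5 were higher and 1 lower, with the same numbers adjusted over the list alone (median 0.22; camera adjusted p = 0.19, and adjusted p = 0.37 with an estimated correlation). Trf, which encodes transferrin, stood at 74.8 ± 10.1 against 35.2 ± 4.68 FPKM (SD, n = 3), Blvrb was higher by 1.40 and Slc11a2 by 0.61, the last a call lost with quantile normalization. The lower member was Lcn2, a call lost without any one resident macrophage library or monocyte-macrophage library 2, while 2 members were lower without monocyte-macrophage library 1 or 3. Handling stress genes showed 1 higher of 19, as they did adjusted over the list alone (camera adjusted p = 0.49, and adjusted p = 0.93 with an estimated correlation); that gene was Jund, with 93.0 ± 13.8 against 52.1 ± 6.81 FPKM (SD, n = 3). The median of the stress list was -0.10 and its mean 0.02. Without monocyte-macrophage library 3, 2 stress genes were lower, and without resident macrophage library 3 or monocyte-macrophage library 1 or 2, 2 were higher.

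Genes associated with tumor macrophages were mostly higher in resident macrophages. Of 19 tested, 15 were higher and 2 lower, with the same numbers adjusted over the list alone (median 1.59; camera adjusted p = 5.8e-05, and adjusted p = 0.20 with an estimated correlation), and 18 of these genes stand in another list too. Arg1, which encodes arginase 1, stood at 408 ± 128 against 94.4 ± 41.8 FPKM (SD, n = 3), and Mrc1 was higher by 3.79. The lower members were Chil3 and Fn1. Of 18 matrix remodeling genes 7 were higher and 6 lower, with the same numbers adjusted over the list alone (median 0.14; camera adjusted p = 0.94, and adjusted p = 0.98 with an estimated correlation). The membrane metalloprotease gene Mmp14 stood at 58.6 ± 2.83 against 9.49 ± 3.62 FPKM (SD, n = 3), Timp2 was higher by 1.88, Plau by 1.69 and Mmp12 by 1.70. Lower members included Vcan (-2.31) and Thbs1 (-1.07). Of 10 growth factor genes 5 were higher, as they were adjusted over the list alone (median 0.84; camera adjusted p = 0.014, and adjusted p = 0.21 with an estimated correlation). Pdgfb, a platelet-derived growth factor gene, stood at 7.40 ± 0.652 against 0.279 ± 0.144 FPKM (SD, n = 3), Vegfb was higher by 2.22 and Gdf3 by 1.06. At a filter of 5 FPKM the growth factor list did not pass camera (adjusted p = 0.066). Of 28 transcription factor genes 14 were higher and 4 lower, or 15 and 4 adjusted over the list alone (median 0.50; camera adjusted p = 0.094, and adjusted p = 0.50 with an estimated correlation). Irf4 stood at 16.2 ± 2.36 against 3.41 ± 0.927 FPKM (SD, n = 3), Relb was higher by 1.70, and Cebpd fell by 1.01. In the same libraries 14 of 16 dendritic cell markers were higher; Batf3 of this list and Ccl22 of the tumor macrophage list are among them. The transcription factor list passed camera with quantile normalization (adjusted p = 0.011), without monocyte-macrophage library 2 (adjusted p = 0.036) and in the 4 libraries with less Y-linked RNA (adjusted p = 0.034).

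Markers of lymphocytes were higher in the resident macrophage libraries. All 20 tested T cell markers were higher, as they were adjusted over the list alone (median 2.28; camera adjusted p = 1.4e-10, and adjusted p = 0.27 with an estimated correlation). Cd3g stood at 57.9 ± 10.3 against 5.66 ± 3.52 FPKM and Cd3e at 39.4 ± 3.75 against 3.84 ± 2.31 (SD, n = 3); Cd4 was higher by 3.44 and Icos by 2.52. Of 8 NK cell markers 7 were higher, and 8 adjusted over the list alone (median 1.39; camera adjusted p = 4.2e-04, and adjusted p = 0.27 with an estimated correlation). The granzyme gene Gzmb stood at 27.5 ± 4.15 against 1.99 ± 2.23 FPKM (SD, n = 3), and Klrd1 and Gzma were higher by 2.07 and 1.91. Of 9 B and plasma cell markers 8 were higher, and 9 adjusted over the list alone (median 2.02; camera adjusted p = 4.3e-04, and adjusted p = 0.27 with an estimated correlation). Cd79a was higher by 2.14 and Cd22 by 1.32. The immunoglobulin gene Igkc was listed at 524, 151 and 144 FPKM in the resident macrophage libraries and at 5.49, 0 and 35.7 in the monocyte-macrophage libraries, a call lost without resident macrophage library 1; that 0 may be a missing value. Ighm stood at 150 ± 142 against 24.6 ± 11.1 FPKM (SD, n = 3), a call lost without any of 4 single libraries. Without resident macrophage library 1, 5 B and plasma cell markers were higher, and at a filter of 5 FPKM that list did not pass camera (adjusted p = 0.067). Of the T cell markers 5, of the NK cell markers 2 and of the B and plasma cell markers 1 reached 1 FPKM in every monocyte-macrophage library.

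Dendritic and mast cell markers moved the same way. Of 16 conventional dendritic cell markers 14 were higher, as they were adjusted over the list alone (median 2.28; camera adjusted p = 1.3e-09, and adjusted p = 0.21 with an estimated correlation). Ccr7 stood at 26.2 ± 5.64 against 0.356 ± 0.287 FPKM and the actin bundling gene Fscn1 at 18.5 ± 8.04 against 0.162 ± 0.147 (SD, n = 3), and Wdfy4 was higher by 0.95. Flt3 and Cd24a had log2 fold changes of 0.41 and -0.48, and Cd24a passed, lower, without monocyte-macrophage library 1. Of the 16 markers 5 stand in another list and 6 reached 1 FPKM in every monocyte-macrophage library. Of 11 plasmacytoid dendritic cell markers 8 were higher and 1, Smim5, lower, or 9 and 1 adjusted over the list alone (median 1.51; camera adjusted p = 8.4e-04, and adjusted p = 0.20 with an estimated correlation). Siglech, which the microglia list also holds, was higher by 1.92 and Pacsin1 by 1.51, while Bst2 and Il3ra, the members with the highest FPKM, had log2 fold changes of 1.02 and 0.12 and did not pass. Bst2 passed without monocyte-macrophage library 3. Of 5 tested markers of mast cells, basophils and eosinophils 4 were higher, as they were adjusted over the list alone (median 3.50; camera adjusted p = 8.5e-04, and adjusted p = 0.27 with an estimated correlation). Tpsb2, a mast cell tryptase gene, was listed at 24.9, 17.7 and 10.2 FPKM against 0, 0 and 0.217, and Cpa3, the mast cell carboxypeptidase gene, at 17.7, 10.7 and 6.90 FPKM against 0 in each monocyte-macrophage library. Of the 5 tested markers of this list 0 reached 1 FPKM in every monocyte-macrophage library. Without a filter 12 members were tested, 7 were higher and the median was 0.74.

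Markers of carcinoma, endothelial, blood and stromal cells were tested as well. Of 6 tested carcinoma markers 4 were higher and 2 lower, with the same numbers adjusted over the list alone (median 1.71; camera adjusted p = 0.12, and adjusted p = 0.29 with an estimated correlation). The higher ones were Axl, Cdh1, Epcam and Krt18, and Met was among those that fell. Cdh1 stood at 21.6 ± 0.552 against 1.71 ± 0.437 FPKM and Epcam at 6.02 ± 1.41 against 0.165 ± 0.105 (SD, n = 3). The keratin gene Krt7 was below the filter, at 0.164 ± 0.0614 and 0.305 ± 0.0875 FPKM (SD, n = 3). Without a filter 5 of 20 carcinoma markers were higher and 2 lower, and the median was 0.09. Of 4 endothelial markers 1, Kdr, was higher and 1, Ly6c1, lower, with the same numbers adjusted over the list alone (median 0.06, mean -0.24; camera adjusted p = 0.89, and adjusted p = 0.97 with an estimated correlation). Of 4 red cell and platelet markers 3 were higher, as they were adjusted over the list alone (median 1.02; camera adjusted p = 0.038, and adjusted p = 0.37 with an estimated correlation). The list did not pass with a pseudocount of 0.1 (adjusted p = 0.087), on the TPM scale (adjusted p = 0.0505) or with quantile normalization (adjusted p = 0.098). It also did not pass without monocyte-macrophage library 1 (adjusted p = 0.063) or 2 (adjusted p = 0.065), or in the 4 libraries with less Y-linked RNA (adjusted p = 0.082). The globin genes Hbb-bt and Hbb-bs were higher by 1.16 and 0.88, both listed at 0 in monocyte-macrophage library 2, and the call of Hbb-bs was lost with quantile normalization, as was that of Kdr (0.94). The fibroblast list had 2 tested members, Ptgds, listed at 0 in monocyte-macrophage libraries 2 and 3, and Col3a1, higher by 1.67 and 0.96, of which Col3a1 did not pass with quantile normalization, and the neural and choroid plexus list 1, the myelin gene Mbp, at 6.55 ± 0.849 against 7.08 ± 0.976 FPKM (SD, n = 3; not passed). Both lists had too few tested members for camera at the main filter. Without a filter 15 fibroblast markers were tested, of which 11 were higher and 0 lower (median 0.31, camera adjusted p = 5.7e-05). In that fit 0 lists passed camera with an estimated correlation.

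**Figure D3:**
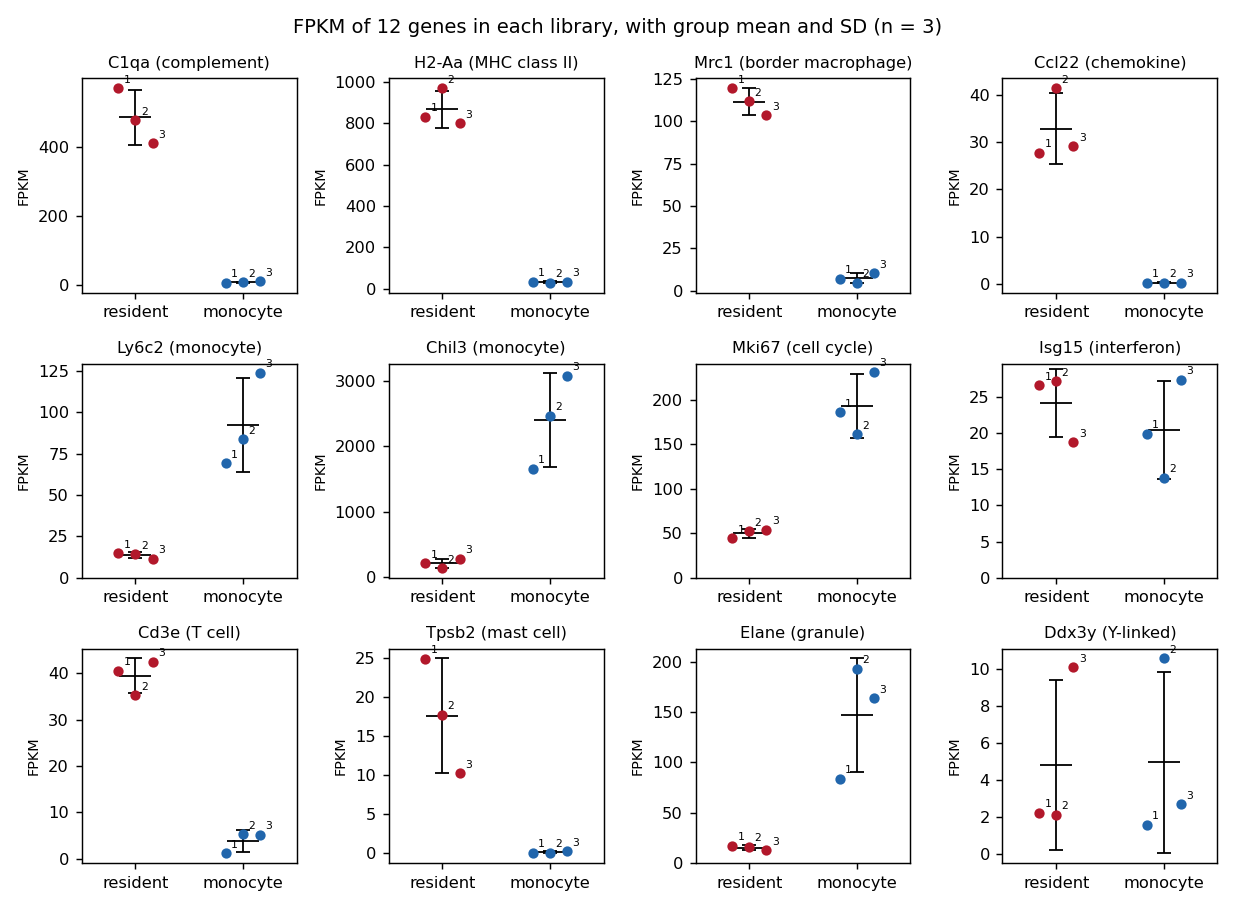
FPKM of 12 genes (y axes, linear scales) in each of the 3 resident macrophage libraries (red) and 3 monocyte-macrophage libraries (blue), numbered by replicate, with the group mean as a bar and the SD as whiskers. C1qa, H2-Aa, Mrc1 and Cd3e lie higher in each resident macrophage library than in any monocyte-macrophage library, Ly6c2, Chil3, Mki67 and Elane lie lower, Isg15 overlaps, and Ddx3y, a Y-linked gene, is highest in resident macrophage library 3 and monocyte-macrophage library 2.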

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

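Most values of named genes and most list tests kept their direction and their side of the threshold. Of the values of named genes under the alternatives 2567 did so, 101 lost the call, 10 gained one and 7 changed sign. Of 621 list tests 574 were the same, 15 were lost, 7 were gained and in 25 the median changed sign. Many named genes were picked from these data for a large change or a small adjusted p, which favours stable calls. Of all 3453 called genes, fewer stayed called when single libraries were left out. The number lay between 2337, without resident macrophage library 2, and 2936, without monocyte-macrophage library 1. No list that passed in either fit changed the sign of its median or its direction in camera, while camera's direction turned in 32 tests of 8 lists that passed in neither. Of the counts, 1247 genes were higher at a filter of 5 FPKM, where 6579 genes were tested and 921 were lower, and fewer genes tested account for part of the loss. An absolute log2 fold change of at least 1 left 883 higher and 428 lower, an adjusted p under 0.01 left 1325 and 646, and the 4 libraries with less Y-linked RNA, a fit chosen after seeing the data, gave 1480 and 780 from fewer libraries. Leaving out single libraries gave between 1590 and 2096 higher, between 780 and 1220 lower, and 23 or 24 lists. Other settings gave 2179 and 1190 with a pseudocount of 0.1, 2888 and 1106 of 22145 genes without a filter, 2245 and 1199 with robust moderation and 2280 and 1194 with library weights. Camera with an estimated correlation passed 0 lists (lowest adjusted p = 0.11), against 24 at the preset correlation and 29 in fry, so list calls rest on the assumed correlation between genes. Fry and camera did not pass the same lists. The neutrophil list passed camera but not fry (fry adjusted p = 0.096). Lists of carcinoma, iron and heme, transcription factor, sort, and Fc and Toll-like receptor genes passed fry but not camera. So did migration and adhesion, up in fry and down in camera. Camera was not run with robust moderation, for which it has no option.

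With a replicate block 1860 genes were higher, 999 lower and 23 lists passed, lipid handling (adjusted p = 0.052) not among them, and Adgre1 lost its call (adjusted p = 0.074). Deviations from the group means of same-numbered libraries correlated at 0.19, -0.15 and -0.09, and resident macrophage library 3 correlated best with monocyte-macrophage library 2 (0.39), so the numbers were not taken as pairs. The values that changed sign were small and none passed, and the cause was not tested. Zfp36 was at 0.08 without resident macrophage library 1 and 0.10 without monocyte-macrophage library 2 (range -0.58 to 0.10). Il3ra was at -0.0937 without resident macrophage library 2 and -0.0201 without monocyte-macrophage library 2 (range -0.0937 to 0.303). Flt1 was at 0.11 without resident macrophage library 3, 0.04 without monocyte-macrophage library 1 (range -0.18 to 0.11) and 0.01 in the 4 libraries with less Y-linked RNA (0.0093463). Medians changed sign at a filter of 5 FPKM for sort genes (0.208) and inflammatory cytokines (-0.103), and on the TPM scale for cytokine receptors (0.0238) and the respiratory chain (0.0179). With median-of-ratios scaling they did for inflammatory cytokines (-0.106), Fc and Toll-like receptors (-0.0940) and endothelial markers (-0.0195). With quantile normalization they did for cytokine receptors (0.0815), Fc and Toll-like receptors (-0.0157), stress genes (0.0307) and endothelial markers (-0.151). Cytokine receptors were at 0.0281 in the 4 libraries with less Y-linked RNA. Leaving out single libraries gave medians from -0.0430 to 0.257 for type I interferon, -0.228 to 0.239 for inflammatory cytokines, -0.0489 to 0.0964 for cytokine receptors, -0.0832 to 0.132 for Fc and Toll-like receptors, -0.313 to 0.0219 for glycolysis, -0.265 to 0.0848 for stress genes and -0.0211 to 0.120 for endothelial markers. The cause was not tested.

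Depth limits genes with few reads: 1 read of a gene with 2 kb of exon is worth 0.0294 to 0.0406 FPKM. In the simulation, with 200 changed genes drawn from expressed genes of any level, 27.3% of 1.5-fold changes were recovered. With 3453 genes called in the data the adjusted threshold is less strict, so this share does not carry over. A gene that did not pass may still differ by that much.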

Other observations

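Further gene groups were put together after the values were seen, so their counts and medians describe the groups and test nothing. All 9 tested genes of T cell activation and regulation were higher in the resident macrophage libraries (median log2 fold change 2.72). Il2ra stood at 12.8 ± 1.40 against 0.476 ± 0.145 FPKM, Tigit at 19.9 ± 2.59 against 1.88 ± 1.47 and Pdcd1 at 14.8 ± 3.82 against 0.826 ± 0.551 (SD, n = 3). Foxp3, the regulator of regulatory T cells, was higher by 2.49 on the log2 scale and was listed at 0 in monocyte-macrophage library 1. All 8 genes of mature dendritic cells were higher (median 3.90). Cacnb3 stood at 15.3 ± 5.80 against 0.120 ± 0.109 FPKM and Zfp366 at 13.4 ± 3.46 against 0.139 ± 0.200 (SD, n = 3). All 5 mast cell genes were higher (median 3.59), with Cma1 listed at 21.3, 16.4 and 10.4 FPKM against 0 in each monocyte-macrophage library.

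Histone genes were the largest further group that was lower in resident macrophages, with 59 of 66 called (median -1.85). Hist1h1e stood at 342 ± 61.0 against 1052 ± 188 FPKM and Hist1h3b at 82.2 ± 17.2 against 410 ± 98.4 (SD, n = 3), and reads of these near-identical genes may be shared. The cyclin genes Ccnd1 and Ccnd2 were higher, at 26.4 ± 6.83 against 1.48 ± 0.590 and 19.4 ± 0.829 against 1.48 ± 0.620 FPKM (SD, n = 3), and Ccnd3 was lower, at 5.18 ± 0.439 against 8.52 ± 0.560 (SD, n = 3). Of 45 ribosomal protein genes 13 were higher (median 0.31). All 5 genes put in the primary granule group were lower (median -2.33), and 5 of 6 in the secondary granule group (median -2.25). The primary group held Elane, Mpo, Prtn3, Ctsg and Ms4a3, of which Ms4a3 encodes a membrane protein and no granule protein.

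The tests of explanations that follow were chosen after these results were seen, except the splits of the libraries. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 3453 genes, and the highest of the others gave 0. For gene lists past camera 1 of 10 reached 24, and the highest of the others gave 17. With 10 splits no share can fall under 0.05, so this test cannot tell.

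The first pattern is the rise of T, NK, B and mast cell markers in resident macrophage libraries, though the gates required CD11b, F4/80 and the reporter. Scaling would bring the median of the T cell markers down, and it was 2.20 with median-of-ratios scaling, against 2.28 as deposited. That scaling moved the median of all genes by -0.09, so the outcome was fixed beforehand. It shows only that a shift of this size is too small to make the rise. A lower share of macrophages alone would raise every other cell type alike. The 11 neutrophil markers outside the primary and secondary granule groups had a median of -0.33 (upper quartile -0.04). The lowest of the lower quartiles of the T, NK, B and mast cell lists was 1.21. Neutrophil RNA in the monocyte-macrophage libraries, which the second pattern below leaves possible, could hide such a rise, so this comparison cannot decide. That these libraries hold RNA of such cells stays open as a hypothesis, since the 20 T cell markers that were higher are the pattern itself and no test of it. Expression by the resident macrophages themselves was not tested on its own. As the sole source it would have to cover markers of several other lineages together. All 20 T cell, 7 of 8 NK cell and 8 of 9 B and plasma cell markers were higher. The same held for 4 of 5 markers of mast cells, basophils and eosinophils. As sets these values argue against it as the sole source, while for single genes it stays open.

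The second pattern is the higher level of granule protein genes in monocyte-macrophage libraries. Mature neutrophils would raise their other markers alike. The comparison used the 11 neutrophil markers outside the primary and secondary granule groups, a split made after the values were seen. Mmp9, which also encodes a granule protein, was among the 11 (log2 fold change 0.20, not passed). Their median log2 difference, monocyte-macrophages minus resident macrophages, was 0.33 (upper quartile 0.51), against 1.38 for the lowest gene of the granule groups. It was 0.75 (upper quartile 1.02, lowest granule gene 2.14) without monocyte-macrophage library 1 and -0.02 without monocyte-macrophage library 2. Without monocyte-macrophage library 3 the margin was narrow, with an upper quartile of 0.59 against 0.66 for the lowest granule gene. Not all of the 11 markers stayed below the granule genes: S100a9 had a log2 fold change of -1.75. In the 11 genes of the granule groups the higher level was not confined to a single library. The middle monocyte-macrophage library lay above the highest resident macrophage library by a median log2 difference of 2.32 (lowest 1.19). These genes were chosen after their values were seen, so this describes them and tests nothing. Monocyte-macrophage library 1 differed among secondary granule genes. It came close for Wfdc21 (30.1, 152 and 303 FPKM in libraries 1, 2 and 3, against 24.6, 22.3 and 21.3). For Ltf it lay at 55.1 FPKM, below resident macrophage libraries 1 and 2 (66.3 and 73.2). For Mmp8 it lay well above, at 127 FPKM against 29.6, 27.3 and 28.3. Whether 1 monocyte-macrophage library carried the calls stays open: the fewest of 7 called neutrophil genes that passed with 1 of them left out was 3, without library 2, where the median log2 fold change was -2.05 (median SE 0.69) against -2.33 (0.61) with all libraries, and 3 also passed without any one resident macrophage library. Immature myeloid cells or young monocytes in the sorted fraction, the biological hypothesis, were not tested.

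The third pattern is Y-linked RNA, higher in resident macrophage library 3 and monocyte-macrophage library 2. If the replicate numbers marked shared mice, same-numbered libraries would have similar levels, but the median ratio of 4 Y-linked genes, monocyte-macrophage library 2 over resident macrophage library 2, was 5.69 (4.78 to 7.33). The median ratio of resident macrophages over monocyte-macrophages was 4.61 for libraries numbered 3 and 1.84 for those numbered 1. Outside the sex genes the deviations of resident macrophage library 3 and monocyte-macrophage library 2 correlated at 0.38, the highest of the 9 pairs across the groups (next 0.19, lowest -0.30). This is consistent with shared mice or handling of these 2 libraries, as a hypothesis. No biological explanation was tested, since the labels give no sex.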
